A study of Mus musculus with 12 samples.

How the data were processed

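Kidneys of untreated wild-type mice were profiled by RNA-seq at day 0 and at day 8 after birth. Per the labels' protocols, total RNA was extracted with a NucleoSpin miRNA column kit, and libraries were made with Illumina's stranded total RNA ligation kit, which removes ribosomal RNA and, with its Plus probe set, globin RNA. Such libraries hold messenger RNA, long noncoding RNA and part of the small nucleolar RNA, but not mature microRNAs. The labels list 12 samples, 6 at each age. Of these, 11 were matched to a column of the series tables by their titles, 6 at day 0 and 5 at day 8. The remaining day 8 sample was not analysed here, so that the tests planned for 6 against 6 libraries were run on 6 against 5. The labels give no sex, litter or batch. They do not say in so many words that each library came from a separate animal, and p-values measure only the spread between these libraries.

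The deposited tables hold estimated counts and TPM for 32692 gene rows, all with a gene symbol. Estimated counts need not be whole numbers: between 12.1% and 13.1% of the values in a library were not whole (any remainder other than 0, without a tolerance), and all were rounded before testing. The deposited TPM values, scaled by the authors for transcript length and library total, sum to between 995005 and 998182 per library. Per the submitters' processing notes, the tools FastQC, fastp, DRAGEN and Picard and the build mm10 were used. Which of them made the counts, with which settings and gene annotation, is not given in the sources used here. Nor is it stated whether counting used the strand, so that a gene overlapping another on the opposite strand, such as Rtl1 and Mir431, may share reads with it. Coordinates and gene types come from GENCODE vM21 on GRCm38, the assembly that mm10 denotes.

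Library totals ranged from 18222170 to 24428652 estimated counts. All 25 pairs of libraries of the same age differed by more than sampling noise, with chi-square per degree of freedom between 4.64 and 41.6 over genes with at least 10 counts, and none was treated as a duplicate. Protein-coding genes took 86.6% of the counts at day 0 and 87.6% at day 8 on average.

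Tests used edgeR 4.0.16 in R 4.3.3: TMM normalisation, the filterByExpr filter, robust quasi-likelihood fits with age as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are TMM-scaled, and errors are SD over libraries unless named SE. The test step was tested on simulated counts with 200 changed genes drawn from the real means and library sizes: for day 8 against day 0, with 18571 genes tested, it recovered 80% of the genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, 50 genes each. Of its 195 calls, 8 were false. In the data a far larger share, 57.6% of tested genes, was called, so that these rates need not hold there.

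The groups, tests, 28 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation of 0.01, log2 CPM with a prior count of 2), adjusted over 27 lists. The sex-linked list served only to check library composition: Xist stood above 2000 CPM in day 0 libraries 2, 5 and 6 and in day 8 libraries 1 and 2, and Ddx3y above 80 CPM in the others. None of its 5 tested genes was called between the ages. Named genes are the tested members of the corticosteroid and Dlk1-Dio3 lists, the 12 highest and 12 lowest log2 fold changes among called genes with a mean CPM of at least 10 and ages that do not overlap, leaving out mitochondrial, small RNA and unnamed genes, and from each other list the 2 members with the largest change and the 2 with the highest level. Of the genes this rule names, 2 are not reported here.

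Alternatives were DESeq2 1.42.0, limma-voom, other normalisations, other filters on low counts, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1, the level of Xist as a covariate, an adjusted p of 0.01, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were run. Leaving out day 0 libraries 1 to 3 or day 8 libraries 3 to 5 was added after seeing the data. Genes with 1 to 3 counts at an age are given with an exact 95% interval of the ratio of counts, which covers counting error only. Genes that share sequence, such as ribosomal protein genes and their pseudogenes, Cyp4a genes and H2 genes, may share reads, and their levels are less certain.

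For microRNA sites, the longest annotated 3' UTR of each gene was taken from GENCODE transcripts, which covered 13752 of 13992 tested protein-coding genes. Figures and site counts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.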

Results

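RNA-seq counts were compared between kidneys of newborn mice (day 0, n = 6 libraries) and 8-day-old mice (day 8, n = 5). Nephron formation in the mouse continues for some days after birth, so that the comparison spans the end of nephrogenesis. The series asks which transcripts differ between these ages, around the regulation of the mineralocorticoid receptor by miR-409-3p and miR-431-5p. Library totals ranged from 18222170 to 24428652 counts. Of 32692 listed genes, 18763 had enough counts to be tested.

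Day 8 kidneys held less RNA of nephron progenitor, fetal growth and imprinted genes, and more RNA of transporters of the mature tubule. Nephron progenitors, the Lin28-let-7 programme and imprinted genes outside the Dlk1-Dio3 domain also passed the list test with an estimated correlation, whereas the tubule lists did not (adjusted p = 0.12 with an estimated correlation for proximal tubule and thick ascending limb, and 0.16 for amino acid transporters). The edgeR quasi-likelihood test called 5162 genes higher and 5646 lower at day 8, which is 57.6% of those tested. Changes of at least 2-fold were called for 906 genes higher and 1091 lower. CPM ranges of the ages did not overlap for 40.5% of genes, against 0.433% by chance. The first principal component separated the ages and held 57.4% of the variance. Libraries of the same age correlated at 0.981 to 0.989 across genes, and libraries of different ages at 0.945 to 0.961. The balance of calls depended on the scale: higher genes were 47.8% of calls with TMM, 39.5% with library size only (4260 higher, 6530 lower) and 68.5% with limma on the deposited TPM values (5424 higher, 2493 lower). The median of all genes was -0.01 (log2) with TMM and 0.13 with TPM, and small changes are relative to it.

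Nr3c2, which encodes the mineralocorticoid receptor, rose 1.89-fold, from 19.9 ± 1.21 CPM (SD, n = 6) at day 0 to 37.6 ± 1.87 CPM (SD, n = 5) at day 8. Its log2 fold change was 0.92 with an SE of 0.05 (edgeR, adjusted p = 1.37e-09), and all 5 day 8 libraries lay above all 6 day 0 libraries. The gene (ENSMUSG00000031618.13) spans positions 76899442 to 77245012 on the plus strand of chromosome 8 in GRCm38. Under the alternatives, its log2 fold change lay between 0.85 and 1.19.

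Other genes of corticosteroid signalling and sodium reabsorption moved in both directions. Of 22 tested members of this list, 10 rose, 5 fell and 7 were not called (11 and 5 adjusted over the list alone). Nr3c1, the glucocorticoid receptor gene, rose from 147 ± 3.81 to 221 ± 5.72 CPM (log2 fold change 0.58). Hsd11b2, whose enzyme inactivates glucocorticoids in aldosterone target cells, rose 2.64-fold from 54.1 ± 6.88 to 143 ± 13.4 CPM, and Hsd11b1, whose enzyme regenerates them, rose 2.20-fold. Klf9, a glucocorticoid-inducible transcription factor gene, rose 1.67-fold, and Edn1, which encodes endothelin-1, 1.78-fold. Atp1b1, a Na,K-ATPase subunit gene, rose 1.39-fold. Nedd4l, a ubiquitin ligase gene for the epithelial sodium channel, rose 1.22-fold, and Cnksr3 rose 1.12-fold, which was not called with library size only (adjusted p = 0.13).

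Fkbp5, a glucocorticoid-induced cochaperone gene, fell 2.41-fold from 54.4 ± 10.8 to 22.6 ± 1.95 CPM (edgeR, adjusted p = 2.76e-06). Zbtb16 stood at 3.81 ± 2.74 CPM at day 0 and 1.16 ± 0.449 CPM at day 8, with a log2 fold change of -1.71 (adjusted p = 0.025). That call was lost when day 0 library 2, 4 or 6 was left out (adjusted p = 0.050, 0.052 and 0.052) or day 8 library 1, 2 or 5 (0.061, 0.057 and 0.063), and with limma-voom (0.058). At day 0, Zbtb16 stood at 6.7925, 5.9971 and 6.1038 CPM in libraries 2, 4 and 6. Libraries 1, 3 and 5 had 1.5082, 1.2938 and 1.1937 CPM, within the day 8 range of 0.70272 to 1.735 CPM. The lower mean at day 8 thus rests mainly on day 0 libraries 2, 4 and 6. The cause of this split was not tested. Fkbp5 was also highest in these day 0 libraries (59.709, 57.624 and 72.033 CPM), but its ages did not overlap. Small decreases were called for Scnn1b (1.19-fold), Elavl1 (1.21-fold) and Zfp36l1 (1.18-fold), and none of the 3 with the TPM values. Sgk1 (-0.07), Tsc22d3 (0.05), Ndrg2 (0.08), Usp2 (-0.03) and the channel subunit genes Scnn1a (0.11) and Scnn1g (0.14) gave log2 fold changes that did not pass. Per1 (-0.38, adjusted p = 0.17) passed without day 0 library 5 (-0.50, adjusted p = 0.030). Scnn1g passed without day 0 library 2 or 5 (adjusted p = 0.014 and 0.036) or day 8 library 1 or 5 (0.039 and 0.040). With all libraries kept, it also passed with RLE normalisation (edgeR, adjusted p = 0.044) and with the level of Xist as a covariate (0.037). The same held without a low-count filter (0.047), with a CPM filter (0.043) and for limma on both TPM versions (0.019 for each). The list as a whole did not pass camera (adjusted p = 0.097, and 0.51 with an estimated correlation), although it did with TPM values (0.042). It also passed fry (adjusted p = 0.000289, direction up).

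**Figure D1:**
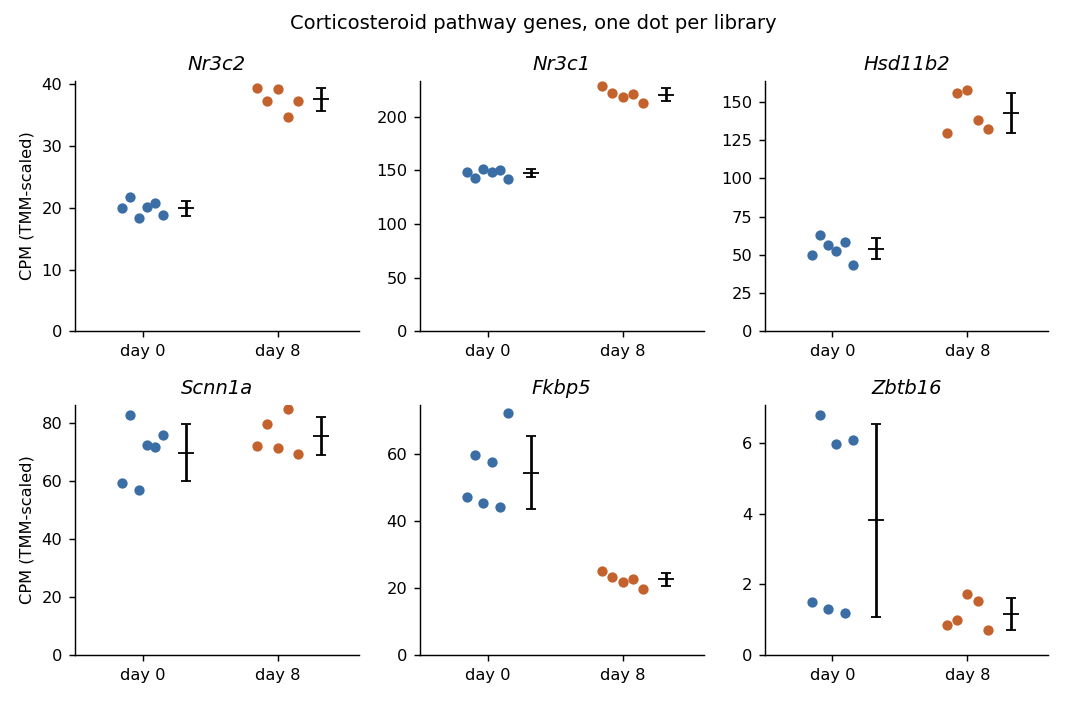
CPM of 6 genes in each library at day 0 (blue, n = 6) and day 8 (orange, n = 5), with the mean and SD as black bars; each vertical axis starts at 0. Nr3c2 lay higher in all 5 day 8 libraries, whereas Scnn1a overlapped between the ages.

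The Dlk1-Dio3 imprinted domain on chromosome 12 holds the microRNA genes named in the series title, and its 4 tested transcripts fell. All 4 were called lower (edgeR; all 4 also adjusted over the list alone). Dlk1, which encodes a growth-regulating transmembrane protein, fell 12.1-fold from 18.3 ± 8.47 CPM (adjusted p = 0.000229), and 33.1-fold without day 8 libraries 3 to 5. The maternally expressed noncoding RNAs Meg3, Rian and Mirg fell 2.53-fold, 2.79-fold and 2.51-fold. Rian went from 55.7 ± 5.83 to 20.0 ± 0.547 CPM, and Mirg from 2.61 ± 0.335 to 1.03 ± 0.278 CPM. Camera gave an adjusted p of 0.0044 for the domain, and adjusted p = 0.18 with an estimated correlation. Rtl1, with 32 counts at day 0 and 2 at day 8, and Dio3, with 13 and 16, were too low to test.

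In GRCm38 the domain runs along the plus strand from Dlk1 (109452823 to 109463336) through Meg3 (109541001 to 109571726), Rian (109603940 to 109661716) and Mirg (109729764 to 109749460) to Dio3 (110279068 to 110281097). The Mir409 hairpin (109743158 to 109743236) lies within Mirg without overlapping any of its annotated exons. The Mir431 hairpin (109590447 to 109590537) lies on the strand opposite to Rtl1 (109589193 to 109600330, minus strand) and overlaps an exon of that gene. Both mature microRNA sequences were found in these hairpins. The annotated 3' UTR of Nr3c2, 2482 bases long, held 1 match to the seed of miR-409-3p and 1 match to the seed of miR-431-5p. Mature microRNAs were not measured in these libraries.

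**Figure D2:**
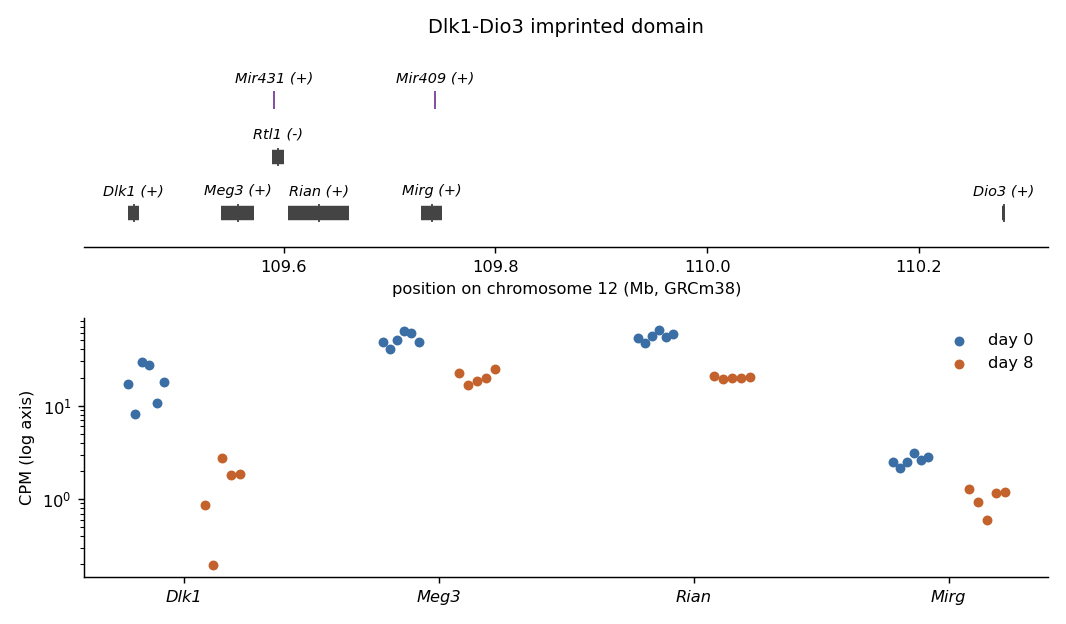
Top, genes and microRNA hairpins of the Dlk1-Dio3 domain to scale along chromosome 12 (Mb, GRCm38), with strand in brackets. Bottom, CPM on a log axis of the 4 tested transcripts in each library at day 0 (blue, n = 6) and day 8 (orange, n = 5); every day 8 library lay below every day 0 library for each transcript.

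Imprinted genes elsewhere in the genome also fell. Of 16 tested members, 13 fell and none rose (camera adjusted p = 5.52e-07, and 0.035 with an estimated correlation). H19, a noncoding RNA of the fetal growth locus, fell 17.9-fold from 1540 ± 173 to 85.9 ± 8.35 CPM, and its neighbour Igf2, which encodes insulin-like growth factor 2, fell 12.5-fold from 1136 ± 96.0 to 91.2 ± 9.41 CPM. Genes of the Lin28-let-7 fetal programme fell in 8 of 9 tested cases (9 adjusted over the list alone; camera adjusted p = 8.76e-06, and 0.028 with an estimated correlation). Hmga2, which encodes a chromatin protein of fetal tissue, fell 7.76-fold, Mycn 4.69-fold, Igf2bp1 2.73-fold and Hmga1 2.61-fold.

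Genes of the nephron progenitor gave some of the largest decreases. Of 15 tested members of this list, 13 fell and 1 rose (camera adjusted p = 2.20e-08, and 0.0054 with an estimated correlation). Six2, the transcription factor gene that maintains the progenitor pool, fell 141-fold from 31.0 ± 1.15 to 0.218 ± 0.110 CPM. Eya1 and Uncx, also transcriptional regulators, fell 43.1-fold and 17.5-fold, and Gdnf, whose product draws out the ureteric bud, fell 39.1-fold. Sall1 fell 2.23-fold. The member that rose, Itga8, did so 1.08-fold with adjusted p = 0.034, and lost its call without day 0 library 2, 4 or 5 (0.051, 0.056 and 0.075) or day 8 library 1 or 2 (0.071 and 0.073), and with library size only (0.35).

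Genes of the early differentiating nephron fell in all 15 tested cases (camera adjusted p = 1.49e-08, and 0.028 with an estimated correlation). Fgf8, a growth factor of the renal vesicle, had 487 counts at day 0 and 1 at day 8, a ratio of 475 with a 95% counting interval of 84.9 to 18799; its single day 8 count lay in library 2, and its fitted log2 fold change was -8.09, or -9.43 without that library. Hes5, a Notch target, had 128 and 3 counts, a ratio of 41.6 with an interval of 13.9 to 204; its log2 fold change was -5.03, or -5.98 without day 8 library 3. Cdh6 fell 1.28-fold and Ccnd1 1.24-fold, the latter not with TPM values (adjusted p = 0.14). In the ureteric bud tip list, 10 of 12 tested genes fell and 1 rose (camera adjusted p = 1.77e-05, but adjusted p = 0.073 with an estimated correlation). Ret, the receptor gene for GDNF, fell 17.7-fold from 35.6 ± 1.56 to 2.02 ± 0.444 CPM. Etv4 and Sox9 fell 13.9-fold and 13.5-fold.

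Cell division genes fell moderately. Of 30 tested members, 29 fell, with a median log2 fold change of -0.50 (camera adjusted p = 2.33e-07, but adjusted p = 0.32 with an estimated correlation). Bub1 and Bub1b, spindle checkpoint genes, fell 1.78-fold and 1.70-fold, and Top2a, a topoisomerase gene of dividing cells, fell 1.61-fold. Mki67 fell 1.29-fold, a call not made with the TPM values (adjusted p = 0.075). By TPM, 21 of the 30 fell.

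Proximal tubule genes rose. Of 26 tested members, 24 rose and none fell, with a median log2 fold change of 1.14 (camera adjusted p = 2.81e-11, but adjusted p = 0.12 with an estimated correlation). Slc5a2, the glucose transporter gene SGLT2, rose 13.4-fold from 20.2 ± 4.25 to 271 ± 29.3 CPM. The sulfate transporter gene Slc13a1 rose 9.63-fold, the phosphate transporter gene Slc34a1 rose 3.25-fold, and Lrp2, which encodes the endocytic receptor megalin, rose 1.74-fold from 3046 ± 289 to 5303 ± 183 CPM. Of 14 amino acid transporters, 12 rose (camera adjusted p = 8.01e-07, but adjusted p = 0.16 with an estimated correlation). Slc6a19, a neutral amino acid transporter gene, rose 5.16-fold, Slc7a8 2.73-fold and Slc3a1 1.95-fold. Slc36a2 was called (3.33, log2), but it followed the fat transcripts: its log2 fold change was 2.74 without day 8 library 3 and 0.57 without day 8 libraries 3 to 5 (adjusted p = 0.33).

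Further along the nephron, 13 of 14 thick ascending limb genes rose (14 adjusted over the list alone; camera adjusted p = 2.20e-08, but adjusted p = 0.12 with an estimated correlation). Egf, which encodes epidermal growth factor, rose 21.2-fold from 7.89 ± 0.661 to 168 ± 26.0 CPM. Umod, the uromodulin gene, rose 4.33-fold, and Slc12a1, the sodium-potassium-chloride cotransporter gene, 1.84-fold. In the distal convoluted and connecting tubule list, 10 of 15 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.000139, but adjusted p = 0.073 with an estimated correlation). Klk1, a kallikrein gene, rose 8.86-fold, Pvalb 6.31-fold, the kinase gene Wnk1 1.69-fold and Slc8a1 1.28-fold.

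The cell types of the collecting duct differed in their counts of calls, although the difference between them was not tested. Of 16 intercalated cell genes, 15 rose (camera adjusted p = 2.67e-06, but adjusted p = 0.15 with an estimated correlation). Slc26a4, the pendrin gene, rose 3.77-fold, Aqp6 2.74-fold, the proton pump subunit gene Atp6v0a4 1.95-fold and Car2, a carbonic anhydrase gene, 1.77-fold. Of 13 principal cell genes, 6 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.48). Gata3 fell 1.97-fold and Tfcp2l1 rose 1.21-fold, whereas the water channel gene Aqp2 had 146 ± 34.6 CPM at day 0 and 144 ± 35.1 CPM at day 8 (adjusted p = 0.95).

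In the podocyte list 8 of 14 genes rose and 4 fell (camera adjusted p = 0.14). Col4a3 and Col4a4, which encode chains of the mature glomerular basement membrane, rose 4.69-fold and 3.56-fold, Wt1 fell 4.03-fold, and Podxl, with 527 ± 19.7 and 541 ± 18.7 CPM, was not called. Endothelial genes rose in 11 of 12 cases (camera adjusted p = 0.000347, but adjusted p = 0.21 with an estimated correlation). Plvap rose 1.79-fold and Cdh5 1.16-fold, whereas Cldn5 fell 1.55-fold. Stroma and matrix genes split, with 10 of 20 higher and 5 lower (camera adjusted p = 0.35); their median was 0.17 and their mean -0.10 (log2). Vcan, a matrix proteoglycan gene, fell 5.47-fold, and Tbx18 fell 4.22-fold, while Col3a1 rose 1.34-fold.

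The renin-angiotensin list had 5 of 10 genes higher and 3 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.35). The number higher stayed at 5 under other scalings. The number lower was 5 with library size only, 1 with TPM values and 1 without day 8 libraries 3 to 5. Agt, the angiotensinogen gene, rose 3.61-fold and Ace 2.32-fold, while the receptor gene Agtr2 fell from 45.8 ± 2.17 to 11.4 ± 2.85 CPM. Fatty acid oxidation genes rose in 17 of 19 cases (camera adjusted p = 1.23e-06, but adjusted p = 0.21 with an estimated correlation). Cyp4a14 rose 12.9-fold, the regulator gene Ppara 2.59-fold and Cpt1a, which encodes the carnitine shuttle enzyme, from 243 ± 9.17 to 341 ± 14.9 CPM. Glycolysis genes went both ways, 7 of 15 higher and 4 lower, although this balance changed to 3 and 4 with library size only, 8 and 1 with TPM values and 3 and 2 without day 8 libraries 3 to 5 (TMM: camera adjusted p = 0.46; median 0.12, mean -0.06). Hk2 fell 3.47-fold and Aldoa rose 1.23-fold.

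**Figure D3:**
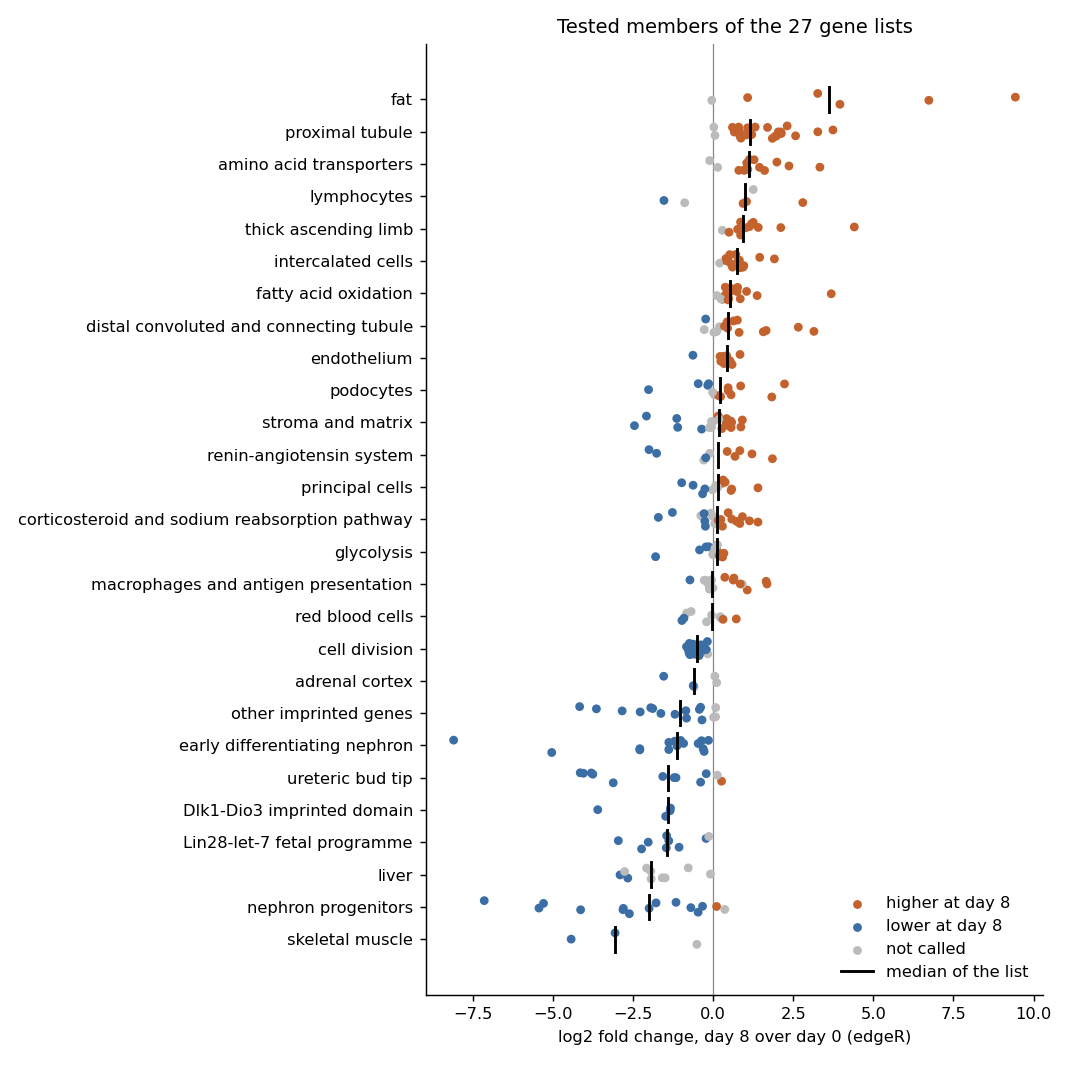
Fitted log2 fold changes, day 8 over day 0 (horizontal axis), of the tested members of 27 gene lists, 1 dot per gene and a black bar at the median of each list. Nephron progenitor genes reached -7.14 (Six2), and 24 of 26 proximal tubule genes were called higher; Fgf8, Hes5, Ucp1 and Cidea rest on 1 to 3 counts at 1 age.

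Outside these lists, the rule for named genes took several more. Kmo, a kynurenine pathway enzyme gene, rose 29.2-fold from 0.724 ± 0.214 to 21.3 ± 1.89 CPM, and Folh1 26.2-fold. Npy6r rose 22.6-fold, Angptl7 21.1-fold, the thyroid hormone deiodinase gene Dio1 by 4.25 (log2), F13b 17.3-fold and Ptgds 15.3-fold. Slc34a3, a phosphate transporter gene, rose 11.7-fold, and G6pc, which encodes glucose-6-phosphatase, 10.3-fold from 53.8 ± 16.7 to 553 ± 104 CPM. The cartilage collagen gene Col2a1 fell 29.8-fold, the axon guidance gene Slit1 20.2-fold and Ndnf 17.5-fold. The adjusted p of these 12 genes lay at or below that of G6pc, 7.25e-07.

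Markers of blood and immune cells changed in part. In the macrophage and antigen presentation list 7 of 18 genes rose and 1 fell (camera adjusted p = 0.31; median -0.03, mean 0.33). H2-Aa and Cd74, genes of antigen presentation, rose 3.21-fold and 3.15-fold and Csf1r 1.29-fold, while Mrc1 was not called (-0.11). Of 6 lymphocyte genes 3 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.46), with Trac 6.96-fold and Ighm 2.06-fold higher and Cd79b 2.89-fold lower. Red blood cell genes gave 2 of 11 higher and 2 lower (camera adjusted p = 0.98, direction down, whereas fry gave up); Bpgm rose 1.24-fold and Epb42 fell 1.88-fold.

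Transcripts typical of fat, liver and skeletal muscle varied between libraries of the same age. Of 6 tested fat genes, 5 rose (camera adjusted p = 0.018, but adjusted p = 0.32 with an estimated correlation); camera gave 0.074 without day 0 library 6, 0.060 without day 8 library 5 and 0.052 without day 8 libraries 3 to 5. Ucp1, the uncoupling protein gene of brown fat, had 2 counts at day 0 and 1767 at day 8, a ratio of 906 with an interval of 250 to 7486. It stood at 33.2, 25.7 and 12.3 CPM in day 8 libraries 3 to 5 and at 3.44 and 3.05 CPM in libraries 1 and 2. Cidea had 3 and 369 counts, a ratio of 126 with an interval of 42.8 to 614. Lpl rose 2.11-fold, and Fabp4 (-0.04) was not called. Without day 8 libraries 3 to 5, 2 fat genes were called higher.

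Of 10 liver genes, 2 fell (camera adjusted p = 0.22). Alb ranged from 90.3 to 158 CPM in day 0 libraries 1 to 3 and from 1.51 to 3.60 CPM in libraries 4 to 6. At day 8, Alb stood at 53.5 and 24.7 CPM in libraries 3 and 4 and at 0.688 to 5.01 CPM in the others, and Ahsg at 16.9 and 7.79 CPM against 0.295 to 2.10 CPM. For Alb, the log2 fold change of -1.93 (adjusted p = 0.26) was -2.92 without day 8 library 3 and 2.85 without day 0 libraries 1 to 3 (adjusted p = 0.16). Without those 3 libraries, 2 of 9 liver genes were higher and 1 lower, with a median of 0.70 against -1.94. Afp fell 6.33-fold, from 65.3 ± 17.8 to 10.3 ± 3.46 CPM, and Ttr 7.48-fold. Without day 0 libraries 1 to 3, Ttr was not called (-2.13, adjusted p = 0.051) and Fgb, not called before (-2.76; called with DESeq2, adjusted p = 0.042), was higher at day 8 (2.18, adjusted p = 0.048). Of 12 skeletal muscle genes, 3 were tested and 2 fell (camera adjusted p = 0.15, and 0.021 to 0.031 with any 1 day 8 library left out). Leaving out libraries can change which members pass the count filter, and without day 8 libraries 3 to 5, 7 were tested. The lower p-values may therefore rest on a different set of genes. Acta1 fell 21.5-fold (log2 fold change -4.43, and -3.70 without day 0 library 1), not called without day 8 libraries 3 to 5 although the value was as large (-4.72, adjusted p = 0.071), and Tnnt3 fell 8.33-fold. Of 5 adrenal cortex genes, 2 fell (camera adjusted p = 0.46). Mc2r fell 2.91-fold, and Akr1b7 fell 1.53-fold, which was lost without day 8 library 1 (adjusted p = 0.051) or 5 (0.060) and without day 0 libraries 1 to 3 (0.23).

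**Figure D4:**
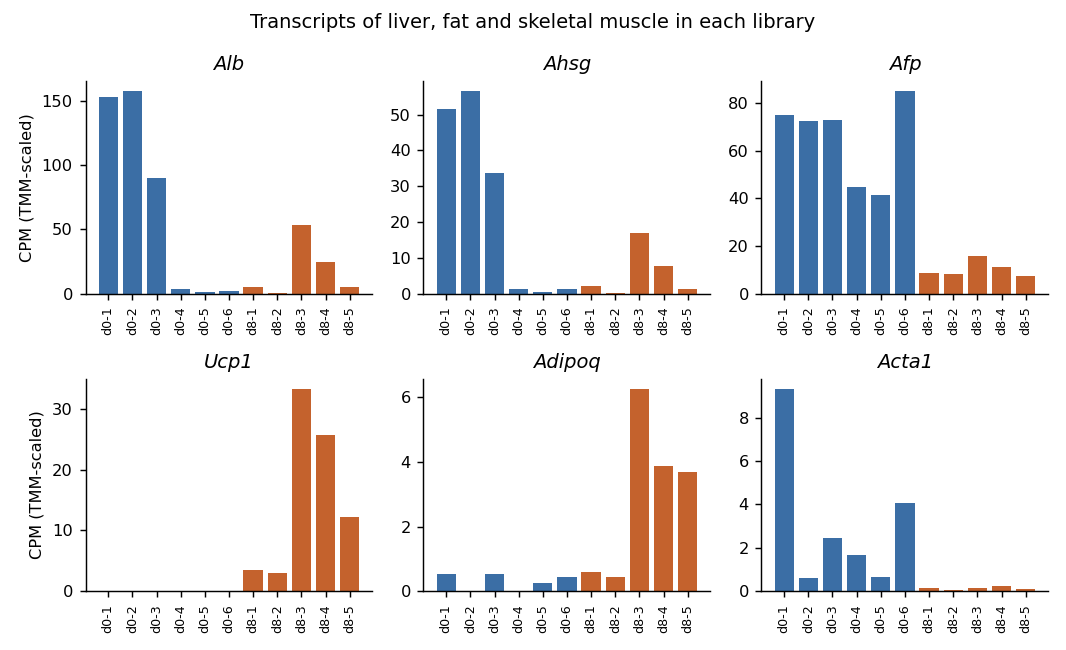
CPM of liver (Alb, Ahsg, Afp), fat (Ucp1, Adipoq) and skeletal muscle (Acta1) transcripts in each library, as bars from 0; d0 and d8 stand for day 0 (blue) and day 8 (orange), followed by the library number. Alb and Ahsg were highest in day 0 libraries 1 to 3, and Ucp1 in day 8 libraries 3 to 5.

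For the lists given with 1 pair of counts, those adjusted over the list alone equalled those over all genes: other imprinted genes, nephron progenitors, early differentiating nephron, ureteric bud tip, cell division, proximal tubule, amino acid transporters, intercalated cells, podocytes, stroma and matrix, endothelium, fatty acid oxidation, glycolysis, macrophages, red blood cells, adrenal cortex, fat, skeletal muscle and liver. Of the 27 lists, 15 passed camera with the preset correlation and 4 with an estimated correlation: other imprinted genes, the Lin28-let-7 programme, nephron progenitors and the early differentiating nephron. Fry, which does not compare a list with the other genes, called 22. Among these, the corticosteroid (fry adjusted p = 0.000289), renin-angiotensin (0.000132), podocyte (2.34e-06) and macrophage (0.0017) lists did not pass camera with TMM. The same held for the skeletal muscle (fry adjusted p = 0.000238), adrenal cortex (0.00846) and lymphocyte (0.0118) lists.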

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

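The groups of values of the named genes reported here were checked for a library far from the others of its age, with the gap to the nearest library set against the whole range (Dixon's 95% criterion on CPM). Of 270 groups, 13 had such a library, where chance gives about 13.5 (1 in 20), so that the number is what chance alone would give. The criterion was first applied to log2(CPM + 0.5), where 12 groups had one, and then to CPM, the scale printed here. No explanation was tested for single values.

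At day 0, library 6 held 4 of them. It had the highest Angptl7 (6.80 CPM, others 2.82 to 4.05), Slc3a1 (215 CPM, others 118 to 153) and Atp6v0a4 (122 CPM, others 84.0 to 96.7), and the lowest Mki67 (324 CPM, others 377 to 405). Library 2 had the highest Aqp2 (212 CPM, others 113 to 143) and Col4a4 (208 CPM, others 178 to 187). Library 3 had the lowest Hk2 (11.3 CPM, others 15.01 to 17.05) and Trac (0.216 CPM, others 0.730 to 0.830).

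At day 8, library 4 had the highest Akr1b7 (12.7 CPM, others 7.69 to 8.99), and library 3 the highest Edn1 (5.21 CPM, others 4.39 to 4.57). Library 2 had the lowest Wnk1 (1118 CPM, others 1187 to 1205) and the single day 8 count of Fgf8 (0.0491 CPM, the others at 0). Library 1 had the lowest Aqp6 (25.7 CPM, others 31.4 to 33.4).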

How the results depend on the processing

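Leaving out day 0 libraries 1 to 3 or day 8 libraries 3 to 5 was chosen after seeing the data. Nr3c2 was called higher under all alternatives run, with log2 fold changes of 0.85 to 1.19 and adjusted p between 2.42e-49 (DESeq2) and 1.17e-06; leaving out 1 library gave 0.89 to 0.95. Leaving out 1 library gave 4863 to 5289 genes higher and 5255 to 5589 lower, 892 to 939 at least 2-fold higher and 1015 to 1173 at least 2-fold lower, and 14 to 16 lists called. With the deposited TPM values, genes lower numbered 2493 (pseudocount 1) and 2487 (pseudocount 0.1), against 5646, and genes at least 2-fold lower 357 and 548, against 1091. The TPM values shift all genes up by a median of 0.13 to 0.15 (log2) and a pseudocount shrinks low genes; the cause beyond that was not tested. With a pseudocount of 1, Six2 fell 20.8-fold, against 141-fold. All 1378 of the 2-fold genes also tested by TPM kept their sign there. Gene lists called fell from 15 to 4 with an estimated correlation, which widens the test where members vary together, and rose to 22 with fry. Of 136 named genes besides Nr3c2, 113 stayed called, or not called, in all alternatives run; uncalled ones such as Alb, Xist and Aqp2 turned sign in some. Fgb alone was called against its earlier sign, at 2.18 (adjusted p = 0.048) without day 0 libraries 1 to 3, which held most of its day 0 counts. Without day 8 libraries 3 to 5, 1986 of 1987 genes changed 2-fold kept their sign. Few counts leave the fold sizes of Fgf8, Hes5, Ucp1 and Cidea uncertain, though not their calls, and 13929 listed genes were not tested.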

Other observations

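The tests of liver carry-over, of Afp, of ribosomal protein genes and their pseudogenes, of the gene families by symbol stem, of splits with an estimated correlation, and 3 of the 4 versions of the seed site test were chosen after the data were seen. Beyond the gene lists, ribosomal protein transcripts were lower at day 8. Of 78 tested ribosomal protein genes, 77 fell and none rose in edgeR, with a median log2 fold change of -0.83, and 74 fell with the TPM values (median -0.69, where the median of all genes was 0.13). Their direction was the same under each scaling run. Small nucleolar RNAs, which guide ribosomal RNA modification, fell in 29 of 51 tested cases, and in 37 of 134 by TPM. Initiation factor genes named Eif fell in 37 of 54 cases and rose in 4, although 13 fell by TPM. Nuclear pore genes named Nup fell in 16 of 21 cases, and in 6 of 19 by TPM. The families Rpl, Rps, Eif and Nup did not pass camera with an estimated correlation (adjusted p = 0.42 for each). Mitochondrial ribosomal protein genes went both ways, with 6 of 48 Mrpl genes higher and 8 lower and 4 of 29 Mrps genes higher and 5 lower.

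Some other families had more genes higher than lower, although no family of 165 passed camera with an estimated correlation. Of 312 tested solute carrier genes named Slc, 176 rose and 52 fell, and of 72 genes named Atp, 46 rose and 7 fell. Lipid transporter genes named Abca rose in 9 of 11 cases (median 0.82), carbonic anhydrase genes named Car in 8 of 12 and peroxisome genes named Pex in 12 of 17. Channel genes went both ways, with 2 of 11 Scn genes higher and 7 lower and 1 of 10 Cacna genes higher and 5 lower, whereas 6 of 12 Kcnj genes were higher and 1 lower. With a preset correlation, camera passed 25 of 165 families; with an estimated correlation, the adjusted p was 0.42 for Slc, Abca, Car and Pex and 0.44 for Atp.

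The age split stood apart from other splits for counts of genes. Of 100 splits of the 11 libraries into 6 and 5, the real one included, 1 gave as many genes in each class, the real one. The real counts were 5162 higher and 5646 lower, against at most 3534 and 3729 in the others, and 906 and 1091 at least 2-fold changed, against at most 571 and 652. The median of the others was 0 for each count. Splits that mix the ages add the age difference to the spread, which lowers their counts. With 100 splits, 1 is also the smallest number possible. The splits cannot tell age from anything else that parted the same groups. The split with the highest counts among the others parted the ages except for 1 day 0 library. For lists called with the preset correlation, 21 of the 100 splits gave at least the real 15, and the highest of the others gave 18. The others among these 21 all held more or fewer than 3 day 0 libraries in the group of 6. They therefore kept part of the age difference. Among splits with 3 day 0 libraries in that group, the highest gave 11 lists. The count of 21 thus cannot say how many lists chance alone gives. With an estimated correlation, added after the preset counts had been seen, 1 split gave the real 4, and the highest of the others gave 2.

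Lower ribosomal protein transcripts could come from a loss of short transcripts at day 8 or from reads assigned to pseudogenes. For 77 ribosomal protein genes, 231 genes were matched on transcript length and level. The ribosomal protein genes were lower by a difference of medians of -0.96 (95% bootstrap interval over genes -1.04 to -0.85). The matched genes had a median of 0.12, which argues against a loss of short transcripts as the whole cause. Their median length of 860 and log2 CPM of 6.86 were close to but not the same as 771 and 7.30. The 125 tested ribosomal protein pseudogenes fell as well (median -0.81, interval over genes -0.84 to -0.73), which argues against a shift of reads to them. Both intervals come from resampling genes as if independent, not libraries. They leave out the spread between libraries. A change with age stays open as an untested hypothesis, and so does a change in cell composition.

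Higher Nr3c2 and lower Dlk1-Dio3 transcripts raise the hypothesis that targets of miR-409-3p and miR-431-5p were released at day 8. In the test as planned, genes with a 3' UTR match to the seed were compared with genes without, and with 209 control 7-mers of the same base composition. For miR-409-3p (1343 genes with a site) the mean difference was -0.03 (log2), and a share of 0.732 of controls was at least as high. By the rule set beforehand, that share argues against a broad release of its targets at the level of RNA. No known release was run for comparison, so that how small a release the test would have seen is not known. For miR-431-5p (1001 genes) the difference was 0.02 and the share 0.124, which leaves release open; 3 further versions gave 0.0606 (controls without CpG), 0.115 (adjusted for 3' UTR length and GC content) and 0.0404 (both), of which those without CpG were run before the planned version, and the 1 value below 0.05 was not planned. Neither test addresses Nr3c2 alone, whose 3' UTR holds 1 site for each, and the microRNAs were not measured.

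Fat and liver transcripts that varied between libraries may come from tissue carried along at dissection. For liver, 8 genes other than Alb and Afp had a median log2 ratio (CPM + 0.05) of 3.41 between the day 0 libraries with the highest and the lowest Alb, in line with carry-over, although Ttr (0.31) hardly followed. The log2 ratio of Afp to Alb ranged over 6.3 among day 0 libraries, which argues against the same source for Afp. For fat, 5 further genes had a median log2 ratio of 0.933 between the day 8 libraries with the highest and lowest Ucp1 (0.65 for Cox7a1 to 2.53 for Thrsp), below the 1 set beforehand, and fat carry-over cannot be told apart from other sources with so few genes; all 5 were also detected at day 0, and from library 2 to library 3 Adipoq went from 0.442 to 6.26 CPM, Plin1 from 1.23 to 16.4, Cidea from 0.491 to 8.31 and Fabp4 from 49.7 to 58.6. At day 8, the libraries with most Ucp1 were also those with Y-linked transcripts, so that sex stays open too, and 2 of them, libraries 3 and 4, had the most Alb.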
